A study of Homo sapiens with 4 samples.

How the data were processed

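RNA sequencing of KP4 cells was analysed in 4 GEO samples, control and E5 cells given DMSO or FOLFIRINOX for 96 h, as total RNA from an RNeasy kit made into libraries with a KAPA mRNA HyperPrep kit, per the labels. Cells were grown in DMEM with 10% FBS. The submitters' processing notes name Trimmomatic, STAR 2.5.1b and build GRCh38. The tables hold 12 columns, 3 numbered columns for each GEO sample, and the column names alone tie them to samples. They were treated as 12 libraries in 4 groups of n = 3, and whether the 3 columns are separate cultures or repeated libraries is not given in the sources used here. No sample column was left out.

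Deposited counts were stranded read counts per gene made with STAR by the authors, without scaling. FPKM values (fragments scaled by gene length and depth) were computed by the authors, and the program is not given in the sources used here. The authors' rlog values were regularised log2 counts per the file headers, and their program is not given either. Gene reads ranged from 7359034 to 21775030 per library over 60651 genes. The 4 classes of reads outside genes stayed out of library sizes: unmapped reads made up 1.47 to 1.70%, multimapping reads 10.79 to 12.84%, reads without a feature 6.63 to 8.52% and reads ambiguous between genes 2.86 to 3.20%.

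Counts were tested with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3, by quasi-likelihood F tests with a group means model, shared dispersion, TMM scaling and filterByExpr, which left 15636 genes, 12650 of them protein coding. Effects common to both lines or treatments were contrasts of this same model. They averaged the drug effects over the lines and the line effects over the treatments. P values were adjusted by the Benjamini-Hochberg method at 0.05. The biological coefficient of variation was 7.37%. Pairs of libraries of a group had a spread of 1.43 to 13.2 times the counting variance. Fitted log2 fold changes used edgeR's default prior count. For a group with 0 counts the floor was 3 counts over the group, and with 1 to 3 counts the ratio is given with its exact counting interval. The plan foresaw counting intervals for single libraries and, in a conditional clause, this replicated test in case the tables held several columns per sample, so the test followed that clause.

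The samples, comparisons, gene lists and most alternatives were chosen before the data were examined. The comparisons were FOLFIRINOX against vehicle in each line, E5 against control cells under each treatment, the difference of the drug responses and the common drug and line effects. Correlations across genes used 15119 genes of at least 1 CPM, with 20 simulations of unchanged genes. Gene length came from the coordinates in the files, in 10 bins, and transcript length and GC content from the longest GENCODE v29 transcript. For the regions, medians of 51 neighbouring tested genes were compared with 1000 shuffles of gene order.

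The 33 gene lists held 722 genes, 590 of them tested, and 29 lists had at least 5 tested genes. They covered p53 targets, mitosis, DNA replication, histone genes, homologous recombination, nucleotide excision repair, secreted inflammatory factors, interferon-stimulated genes, antigen presentation, drug transport and metabolism, metallothioneins, NRF2 targets, cholesterol synthesis, ATF4 targets, ER chaperones, mesenchymal and matrix genes, epithelial genes, classical and basal-like pancreatic tumour genes, lysosome, stemness, BCL2 family, hypoxia and glycolysis, ribosome biogenesis, ribosomal proteins, mitochondrially encoded genes, YAP targets, MAPK output, senescence markers and markers of other cell types. Each median log2 fold change was set against 10000 random lists matched on expression in 20 bins. Since genes of a list vary together, camera with an estimated correlation was run as well, and a list is said to have risen or fallen only if this test passed. Of 203 pairs of list and comparison, 95 lay outside the central 95% of random lists, where chance gives 5%, and 25 passed camera with an estimated correlation. With camera's preset correlation of 0.01, 71 pairs passed, so which lists pass depends on this choice.

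Named genes followed a rule set in the plan. For 2 groups these were the 10 highest and 10 lowest folds among protein-coding genes that passed the test and reached 5 CPM in any library of those groups. For common effects they were the 10 smallest p in each direction at a mean of at least 5 CPM and a fold of at least 2. For the difference they were the 10 largest in each direction among genes that passed the test and reached 5 CPM in any library. In lists outside the central 95% of random lists, the 4 genes of at least 1 CPM with the largest change were added, along with CDKN1A, MDM2, GDF15, MKI67, TOP2A, TYMS, TOP1, TK1, DPYD, ABCB1, ABCC2, ABCG2, CES2, SLC29A1 and ATP7B in each comparison. Some genes that this rule names are not reported here. Where no adjusted p stands beside a gene said to have changed, it was under 0.05.

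Alternatives were DESeq2 1.42.0, DESeq2 size factors, total counts only, no filter, genes of at least 10 CPM, a fold of at least 2 as well, the authors' FPKM as log2(FPKM + 1) and log2(FPKM + 0.1), their rlog values, limma-voom, prior counts of 0.5 and 10, thinning to 7359034 reads, the library number as a block, and leaving out each library in turn. A GC correction, more settings for the correlations, camera for the lists and 2000 random lists for the left-out libraries were added later. The test was tried on simulated data of 15636 genes with 200 changed. In control cells it found 33 of 66 genes changed by log2 0.5, 60 of 67 by 1 and 63 of 67 by 2, with 8 false among 164 calls. For the difference it found 14 of 66, 56 of 67 and 54 of 67, with 9 false among 133. The simulated noise was independent between libraries and few genes changed, whereas 65.3% of genes were called for the drug in control cells. These figures therefore do not test scaling or error control under conditions like those of the data.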

Results

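KP4, a human pancreatic ductal adenocarcinoma line, was profiled by RNA sequencing as control cells and as cells called E5. Each kind of cell was given vehicle (DMSO) or FOLFIRINOX for 96 h. The FOLFIRINOX mixture held 25 nM SN-38, the active form of irinotecan, with 10 µM of an agent written as 5-F and 5 µM oxaliplatin, a platinum compound. The study's title calls the E5 cells resistant and has them given vehicle or drug for 96 h, whereas its design text speaks of 5 cycles of the same treatment, so what the E5 vehicle cells met earlier is not settled here. The 4 GEO samples each came with 3 numbered columns, read here as 12 libraries in 4 groups of n = 3. The spread between libraries is therefore between columns of 1 GEO sample and may be technical. Reads assigned to genes numbered 9230058, 21775030 and 18061835 in control vehicle libraries and 7359034, 18648486 and 17094249 in control FOLFIRINOX libraries. E5 vehicle libraries held 7766074, 16581709 and 12232329 and E5 FOLFIRINOX libraries 19118134, 13940396 and 15501024. Levels are CPM (counts scaled for library depth by TMM) as mean ± SD of n = 3 libraries, and log2 fold changes are given ± SE. A count of 0 over a group allows up to 3 counts, which is 0.0633 CPM in control vehicle, 0.0654 in control FOLFIRINOX, 0.0854 in E5 vehicle and 0.0613 in E5 FOLFIRINOX. Such floors and all 95% intervals of ratios cover counting error only.

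The 12 libraries fell into their 4 groups on the leading principal components of log2 CPM. The axis with 48.7% of the variance parted the lines, with E5 libraries at 27.56 to 67.46 and control libraries at -71.16 to -24.42. The next axis, with 34.2%, parted the treatments, with vehicle libraries at 12.02 to 66.21 and FOLFIRINOX libraries at -47.32 to -28.97.

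**Figure D1:**
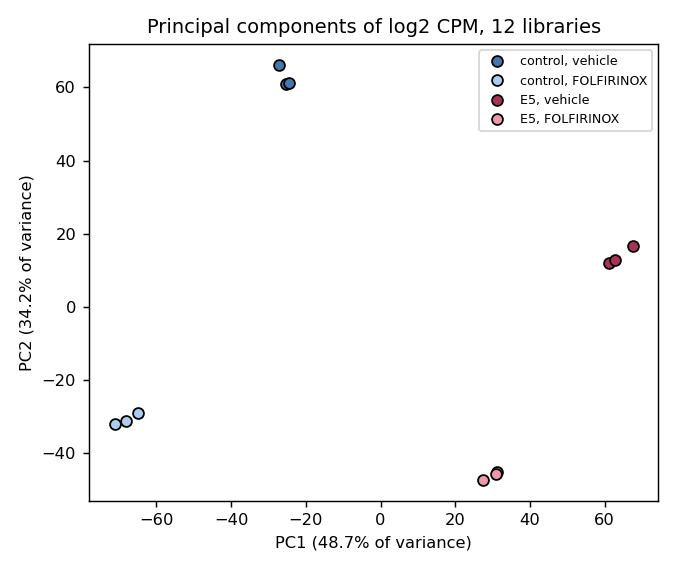
Principal components of log2 CPM for the 12 libraries, with PC1 (48.7% of variance) on the x axis and PC2 (34.2%) on the y axis, both in arbitrary units. Each point is a library coloured by group, and on PC2 the vehicle libraries lie at 12.02 or above and the FOLFIRINOX libraries at -28.97 or below.

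The response of control cells to the drug was read from FOLFIRINOX against vehicle. Histone genes and ribosome biogenesis genes rose as lists and cholesterol synthesis genes fell. TXNIP, which encodes a thioredoxin-binding protein (ENSG00000265972.6, chromosome 1, 145992435 to 145996579, GRCh38), rose from 9.51 ± 0.759 to 232 ± 5.57 CPM, a log2 fold change of 4.61 ± 0.077, adjusted p = 1.3e-16. IL1RL1, which encodes the interleukin-33 receptor (ENSG00000115602.17, chromosome 2, 102311502 to 102352037), rose 82.3-fold (95% interval 27.8 to 402) from 3 counts over the control vehicle libraries. PADI2, an enzyme that turns arginine into citrulline (ENSG00000117115.13, chromosome 1, 17066761 to 17119451), fell from 466 ± 13.8 to 20.2 ± 2.42 CPM, log2 -4.54 ± 0.083, adjusted p = 3.2e-16.

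The other protein-coding genes with the highest folds in control cells included enzymes and receptors. VNN1, a pantetheinase, rose by log2 5.2 ± 0.36, the aldehyde oxidase AOX1 by 5.01 ± 0.29 and the phospholipase PLA2G4C by 4.64 ± 0.2. The tyrosine kinase BTK rose by 4.50 ± 0.26, the prolactin receptor PRLR by 4.03 ± 0.27, and DACT1, RRAD and BTG4 by 4.17 ± 0.23, 4.11 ± 0.34 and 3.94 ± 0.31. Among the genes with the lowest folds, the calcium-binding protein CALB1 had -3.81 ± 0.36, SNED1 -3.79 ± 0.19, the microtubule-associated protein MAP1A -3.65 ± 0.11 and the citrullinating enzyme PADI3 -3.42 ± 0.14. PIR, a nuclear iron-binding protein, fell at -3.50 ± 0.077, the neurotensin receptor NTSR1 at -3.16 ± 0.12, the ferroptosis suppressor AIFM2 at -3.14 ± 0.22, the sterol carrier STARD4 at -3.14 ± 0.15 and the transcription factor GRHL3 at -3.00 ± 0.22. Each of these genes had an adjusted p of at most 7e-08.

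The libraries came from an mRNA kit, so histone values in every comparison cover only the transcripts that it captured. Of the histone list, 12 of 14 tested genes rose, 0 fell and 2 did not pass (13 and 0 adjusted over the list alone) in control cells. Its median log2 fold change was 1.5 (adjusted p = 0.0081 with an estimated correlation), with H2BC15 at 2.47 ± 0.14 and H4C8 at 2.02 ± 0.1. Among ribosome biogenesis genes, 21 of 26 tested genes rose, 3 fell and 2 did not pass, median 0.54 (adjusted p = 0.015 with an estimated correlation). The transcription factor MYC rose by 1.05 ± 0.07 and the nucleolar protein NOP56 by 0.75 ± 0.052. In the cholesterol synthesis list, 0 of 22 tested genes rose, 21 fell and 1 did not pass, median -1.05 (adjusted p = 0.0081 with an estimated correlation). INSIG1, a brake on sterol synthesis that is itself sterol-regulated, fell at -2.34 ± 0.073 and the transcription factor SREBF2 at -2.27 ± 0.084. Counts adjusted over the list alone were equal for the ribosome biogenesis and cholesterol synthesis lists.

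Secreted inflammatory factors moved in number, although the list test did not pass. Of them, 18 of 21 tested genes rose, 2 fell and 1 did not pass, median 1.43, with adjusted p = 0.058 with an estimated correlation. The cytokine genes IL1A and IL1B rose by 3.13 ± 0.42 and 3.01 ± 0.29, and the chemokine genes CXCL8 and CXCL5 by 3.08 ± 0.097 and 2.78 ± 0.19. Among genes of the MAPK and AP-1 output list, 13 of 21 tested genes rose, 3 fell and 5 did not pass, median 0.21, with adjusted p = 0.63 with an estimated correlation. The phosphatase DUSP5 rose by 2.57 ± 0.088 and the AP-1 subunit FOSL1 by 1.61 ± 0.091. In the interferon-stimulated list, 4 of 31 tested genes rose, 11 fell and 16 did not pass, median -0.47 (-0.31 with BST2 at its floor bound), with adjusted p = 0.83 with an estimated correlation. The antiviral genes OAS2 (-1.82 ± 0.39) and CMPK2 (-1.81 ± 0.35) fell, calls that were lost on the authors' values as log2(FPKM + 1) (OAS2 -0.18, CMPK2 -0.29). In the antigen presentation list, 11 of 20 tested genes rose, 5 fell and 4 did not pass, median 0.31 and mean 0.08, with adjusted p = 0.83 with an estimated correlation. HLA-B rose by 1.20 ± 0.08 and TAPBP, a peptide-loading factor, fell at -1.30 ± 0.076. The immunoproteasome subunit PSMB10 fell at -1.24 ± 0.23 by counts but lay at 0.12 and 0.11 by the authors' FPKM. All these counts were equal when adjusted over the list alone.

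The lists of cell division genes, p53 targets and stress genes did not pass the list test in control cells. In the DNA replication list, 4 of 37 tested genes rose, 26 fell and 7 did not pass, median -0.38, with adjusted p = 0.32 with an estimated correlation. The DNA ligase LIG1 fell at -1.34 ± 0.091, thymidine kinase TK1 at -0.92 ± 0.091, the polymerase subunit POLA1 at -0.83 ± 0.063 and the sliding clamp PCNA at -0.83 ± 0.064. In the mitosis list, 13 of 31 tested genes rose, 6 fell and 12 did not pass, median 0.07, with adjusted p = 0.83 with an estimated correlation. HMMR and UBE2C, both active in mitosis, rose by 0.73 ± 0.14 and 0.66 ± 0.076, while the proliferation marker MKI67 fell at -0.79 ± 0.085. Of p53 targets, 11 of 31 tested genes rose, 12 fell and 8 did not pass, median -0.06 and mean 0.04, with adjusted p = 0.74 with an estimated correlation. The cell cycle inhibitor CDKN1A rose by 0.69 ± 0.09, whereas the p53 ligase MDM2 fell at -1.12 ± 0.093 and the stress cytokine GDF15 at -0.89 ± 0.15. Transcripts of the mitochondrial genome were mostly lower: 1 of 13 tested genes rose, 12 fell and 0 did not pass, median -0.70, with adjusted p = 0.57 with an estimated correlation and MT-CO2 at -1.10 ± 0.062. In the list of endoplasmic reticulum chaperones, 2 of 18 tested genes rose, 11 fell and 5 did not pass, median -0.41, with adjusted p = 0.085 with an estimated correlation and PDIA4 at -0.84 ± 0.055. Of NRF2 targets, 3 of 19 tested genes rose, 10 fell and 6 did not pass, median -0.37, with adjusted p = 0.085 with an estimated correlation. Counts adjusted over the list alone were equal for these lists.

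Among genes tied to the drugs, DPYD, which breaks down fluoropyrimidines, fell at -1.36 ± 0.073, and the efflux pumps ABCC2 and ABCG2 rose by 1.12 ± 0.11 and 0.57 ± 0.069. TOP1, the enzyme that SN-38 poisons, rose by 0.27 ± 0.071, adjusted p = 0.0029. TYMS, the thymidylate synthase, stood at -0.09 ± 0.06, adjusted p = 0.17, the pump ABCB1 at 0.31 ± 0.29, adjusted p = 0.45 and the copper transporter ATP7B at -0.06 ± 0.16, adjusted p = 0.75. CES2, which activates irinotecan, fell at -0.38 ± 0.093 by counts and lay at 0.00 by the authors' FPKM. TOP2A (0.32 ± 0.13, adjusted p = 0.037) passed the test with all libraries, but not without control FOLFIRINOX replicate 1 (0.24) or 3 (0.23) or control vehicle replicate 1 (0.34) or 3 (0.25). The nucleoside transporter SLC29A1 (0.20 ± 0.081, adjusted p = 0.04) passed with all libraries, but not without control FOLFIRINOX replicate 2 (0.12), control vehicle replicate 1 (0.22), 2 (0.19) or 3 (0.19) or E5 vehicle replicate 2 (0.20). Of the named genes past the test, TOP2A had libraries that overlapped between the groups. In all, 10203 of 15636 tested genes passed at an adjusted p under 0.05, 5094 higher and 5109 lower, with 1833 and 1280 of them at least 2-fold. On log2(FPKM + 1) the all-gene median lay 0.15 above 0, and 5708 genes were higher and 2792 lower.

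In E5 cells the question was which genes answered the same 96 h of drug. Interferon-stimulated genes, cholesterol synthesis genes and chaperones of the endoplasmic reticulum fell as lists, and histone and ribosome biogenesis genes rose. MX1, an antiviral GTPase (ENSG00000157601.15, chromosome 21, 41420020 to 41470071), fell from 156 ± 26.1 to 18.7 ± 1.57 CPM, log2 -3.06 ± 0.12, adjusted p = 8.9e-12. TXNIP rose from 18.7 ± 0.956 to 129 ± 3.19 CPM (2.78 ± 0.072, adjusted p = 8.5e-14), and IL1RL1 rose by 4.14 ± 0.28.

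Other genes with the highest folds in E5 cells were the chemokine receptor ACKR3 (3.70 ± 0.23), the axon guidance factor DRAXIN (3.53 ± 0.3), DMKN (3.22 ± 0.21) and the cGMP-dependent kinase PRKG1 (3.16 ± 0.31). The deacetylase HDAC9 rose by 3.12 ± 0.094, AOX1 by 3.03 ± 0.25, MARCHF4 by 2.87 ± 0.18 and the lipid carrier APOE by 2.65 ± 0.12. The 10 with the lowest folds included IFI44L (-3.47 ± 0.24), OAS2 (-2.70 ± 0.093) and IFIT1 (-2.48 ± 0.11) of the interferon-stimulated list, and IFITM1 (-2.82 ± 0.27), which is not in that list. PADI3 (-2.97 ± 0.12), AIFM2 (-2.72 ± 0.17) and the synaptic protein UNC13A (-2.77 ± 0.17) were also among the 10. Each named gene of these had an adjusted p of at most 3.5e-07.

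Of the interferon-stimulated list, 0 of 31 tested genes rose, 28 fell and 3 did not pass, with a median of -1.67 (adjusted p = 0.0005 with an estimated correlation) and BST2 at -4.09 ± 0.3. Among cholesterol synthesis genes, 0 of 22 tested genes rose, 20 fell and 2 did not pass, median -1.16 (adjusted p = 0.00024 with an estimated correlation). HMGCS1, an early enzyme of the pathway, fell at -1.72 ± 0.077 and INSIG1 at -2.0 ± 0.07. In the chaperone list, 1 of 18 tested genes rose, 16 fell and 1 did not pass (1 and 17 adjusted over the list alone), median -0.52 (adjusted p = 0.0023 with an estimated correlation), with HERPUD1 at -1.25 ± 0.07 and the abundant chaperone HSPA5 at -1.03 ± 0.046. For histone genes, 13 of 14 tested genes rose, 0 fell and 1 did not pass, median 0.71 (adjusted p = 0.0051 with an estimated correlation), with H2BC15 at 1.71 ± 0.14 and H2AC6 at 1.44 ± 0.068. For ribosome biogenesis, 18 of 26 tested genes rose, 0 fell and 8 did not pass (19 and 0 adjusted over the list alone), median 0.36 (adjusted p = 0.0051 with an estimated correlation), with WDR43 at 0.84 ± 0.057 and MYC at 0.68 ± 0.071. Counts adjusted over the list alone were equal for the interferon-stimulated, cholesterol and histone lists.

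Several further lists held called genes in E5 cells without a passing list test, where 52.3% of all tested genes were called. In the antigen presentation list, 1 of 20 tested genes rose, 17 fell and 2 did not pass, median -0.53, with adjusted p = 0.067 with an estimated correlation, HLA-F at -1.18 ± 0.12 and TAPBP at -1.08 ± 0.073. Of secreted inflammatory factors, 11 of 21 tested genes rose, 3 fell and 7 did not pass, median 0.29, with adjusted p = 0.32 with an estimated correlation, IL1A at 1.34 ± 0.19 and the protease MMP10 at -0.94 ± 0.16. Of ATF4 targets, 7 of 21 tested genes rose, 12 fell and 2 did not pass (7 and 13 adjusted over the list alone), median -0.64, with adjusted p = 0.4 with an estimated correlation. The serine synthesis enzyme PSAT1 fell at -1.89 ± 0.058, CHAC1 fell at -2.17 ± 0.18 and the phosphatase regulator PPP1R15A rose by 1.85 ± 0.1. In the DNA replication list, 3 of 37 tested genes rose, 18 fell and 16 did not pass, median -0.20, with adjusted p = 0.39 with an estimated correlation and LIG1 at -1.10 ± 0.092. Of p53 targets, 7 of 31 tested genes rose, 14 fell and 10 did not pass, median -0.25, with adjusted p = 0.55 with an estimated correlation, FDXR at -1.70 ± 0.14 and the growth arrest gene GADD45A at 1.27 ± 0.075. Of mitochondrially encoded genes, 1 of 13 tested genes rose, 11 fell and 1 did not pass (1 and 12 adjusted over the list alone), median -0.56, with adjusted p = 0.39 with an estimated correlation. Of ribosomal protein genes, 14 of 28 tested genes rose, 2 fell and 12 did not pass (17 and 2 adjusted over the list alone), median 0.20, with adjusted p = 0.63 with an estimated correlation and RPL6 at 0.62 ± 0.055. Of MAPK and AP-1 output genes, 12 of 21 tested genes rose, 4 fell and 5 did not pass, median 0.26, with adjusted p = 0.63 with an estimated correlation, FOSL1 at 1.35 ± 0.091 and EGR1 at -1.15 ± 0.084. Of epithelial genes, 2 of 13 tested genes rose, 7 fell and 4 did not pass, median -0.39, with adjusted p = 0.39 with an estimated correlation and the adhesion gene CDH1 at -1.91 ± 0.29. The list's median was 0.00 on log2(FPKM + 1). Where no second count stands, the count adjusted over the list alone was equal.

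Among the genes tied to the drugs, SLC29A1 rose by 0.68 ± 0.087 in E5 cells, CES2 fell at -0.40 ± 0.093, MDM2 at -0.66 ± 0.091, GDF15 at -1.01 ± 0.15, MKI67 at -0.87 ± 0.085 and TK1 at -0.93 ± 0.092. ABCG2 stood at 0.21 ± 0.061, adjusted p = 0.0081, a call lost without E5 vehicle replicate 1 (0.15) and on the authors' FPKM (0.14). Changes of CDKN1A (0.15 ± 0.09, adjusted p = 0.17), DPYD (-0.01 ± 0.073, adjusted p = 0.91), TYMS (0.05 ± 0.06, adjusted p = 0.52), TOP1 (0.10 ± 0.072, adjusted p = 0.26) and TOP2A (0.25 ± 0.13, adjusted p = 0.11) did not pass with all libraries. The same held for ABCC2 (0.11 ± 0.091, adjusted p = 0.34), ATP7B (-0.24 ± 0.16, adjusted p = 0.23) and ABCB1 (-0.44 ± 0.19, adjusted p = 0.064). Under other settings CDKN1A passed with the GC correction (0.34), TOP1 with total counts only (0.17), and ABCC2 on the authors' FPKM (0.49 and 0.66). ABCB1 passed without E5 vehicle replicate 1 (-0.52), with the GC correction (-0.49) and on log2(FPKM + 1) (-0.46), and TOP2A passed without control FOLFIRINOX replicate 2 (0.26), with no filter (0.26) and with total counts only (0.32). The test called 8174 genes, 3909 higher and 4265 lower, with 928 and 667 at least 2-fold. On log2(FPKM + 1) 3678 genes were higher and 2661 lower.

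**Figure D2:**
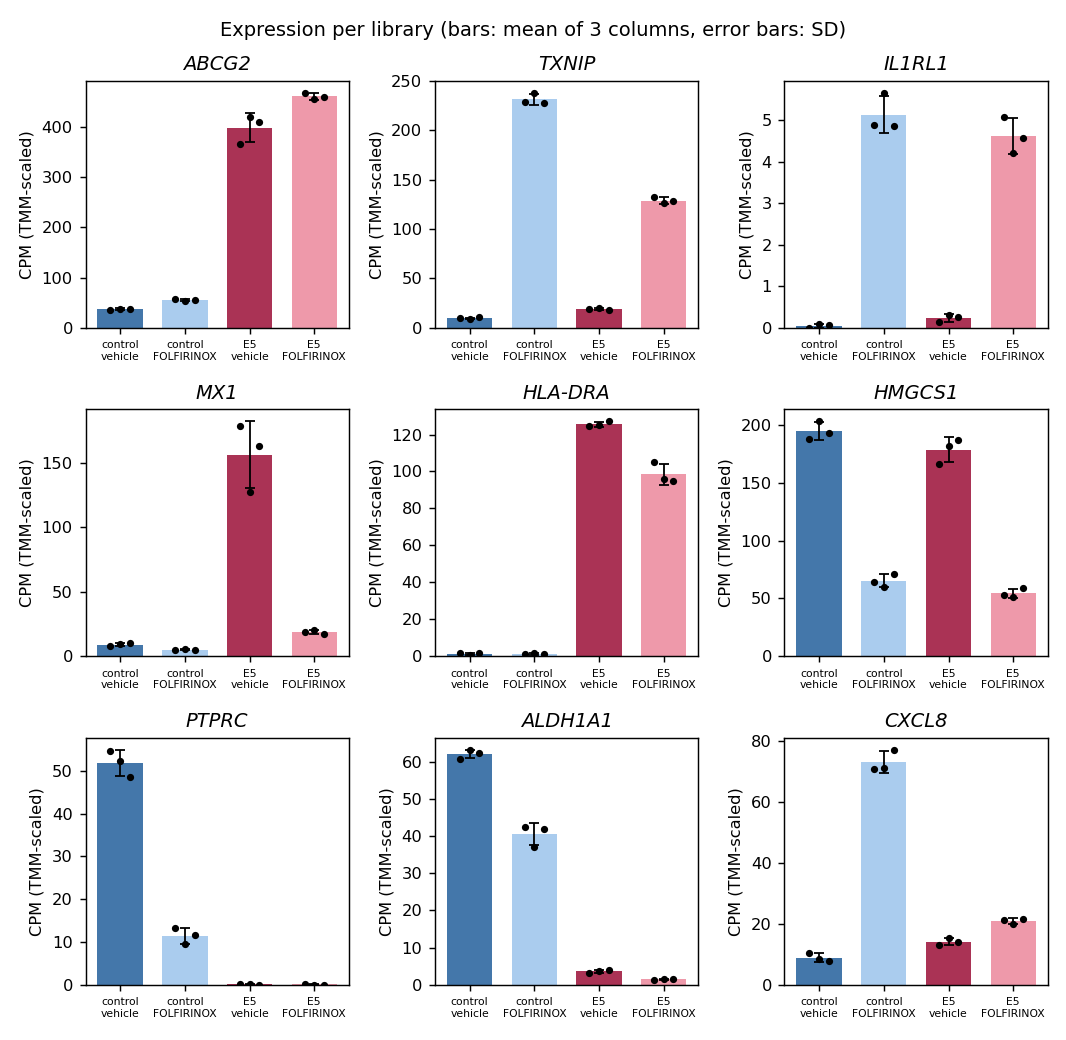
CPM (y axis, TMM-scaled) of 9 genes in control and E5 cells given vehicle or FOLFIRINOX. Bars are means of n = 3 libraries, error bars SD and points libraries, and ABCG2 stood at 36.7 ± 2.02 CPM in control vehicle and 398 ± 28.9 CPM in E5 vehicle libraries.

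The lines themselves were compared under vehicle, E5 against control. E5 cells carried more transcripts of antigen presentation genes, interferon-stimulated genes, NRF2 targets, epithelial genes and histone genes. HLA-DRA, an MHC class II chain (ENSG00000204287.14, chromosome 6, 32439878 to 32445046), stood at 1.25 ± 0.425 CPM in control and 126 ± 1.47 CPM in E5 libraries, log2 6.71 ± 0.15, adjusted p = 1e-15. The drug efflux pump ABCG2 (ENSG00000118777.12, chromosome 4, 88090150 to 88231628) stood at 36.7 ± 2.02 and 398 ± 28.9 CPM, log2 3.44 ± 0.07, adjusted p = 7.8e-16. PTPRC, the leukocyte phosphatase CD45 (ENSG00000081237.20, chromosome 1, 198638457 to 198757476), stood at 51.9 ± 3.1 CPM in control and 0.0656 ± 0.067 CPM in E5 libraries, which is 903-fold (95% interval 250 to 7460) lower in E5 cells.

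Of the genes with the highest folds in E5 cells, the guanine deaminase GDA had a log2 of 8.30 ± 0.14 and the interferon-inducible IFI44L 7.23 ± 0.39. The synaptic protein NRXN3 had 0 counts in control libraries and was at least 289-fold higher in E5 cells. From 1 to 3 counts in control libraries, ARHGAP20 was 1030-fold (95% interval 283 to 8470) higher, HLA-DPB1 478-fold (95% interval 85.2 to 18900), the adhesion molecule VCAM1 412-fold (95% interval 73.3 to 16300) and the water channel AQP4 367-fold (95% interval 65.3 to 14600). The laminin chain LAMA4 was 270-fold (95% interval 47.9 to 10700) higher, HS6ST3 206-fold (95% interval 69.9 to 1000) and the retinoic acid receptor RARB 209-fold (95% interval 57.4 to 1740). In the other direction, SULT1B1 was 305-fold (95% interval 54.5 to 12100) and SCEL 237-fold (95% interval 80.7 to 1150) lower in E5 cells. RAB34 stood at -6.16 ± 0.27, the peptidases TRHDE and MME at -6.07 ± 0.19 and -5.91 ± 0.2, CPED1 at -5.61 ± 0.14 and CALB1 at -5.06 ± 0.47. The cadherin-like genes PCDHAC1 and PCDH15 stood at -4.92 ± 0.35 and -4.91 ± 0.25.

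Of the antigen presentation list, 20 of 20 tested genes were higher, 0 were lower and 0 did not pass, with a median of 1.80 (adjusted p = 0.00082 with an estimated correlation). CD74, the invariant chain, stood at 6.08 ± 0.12, HLA-DRB1 at 5.68 ± 0.14 and CIITA, the class II transactivator, at 4.51 ± 0.2. Of interferon-stimulated genes, 29 of 31 tested genes were higher, 0 were lower and 2 did not pass (30 and 0 adjusted over the list alone), median 2.45 (adjusted p = 0.0012 with an estimated correlation), with OAS2 at 6.19 ± 0.14 and SAMD9L at 5.69 ± 0.34. Among 12 leukocyte markers, PTPRC was the only member to reach 1 CPM in control libraries, and 0 reached it in E5 libraries. Of NRF2 targets, 18 of 19 tested genes were higher, 0 were lower and 1 did not pass, median 1.01 (adjusted p = 0.0032 with an estimated correlation). The reductases AKR1B10 and AKR1C3 stood at 3.42 ± 0.26 and 3.22 ± 0.43. Of epithelial genes, 9 of 13 tested genes were higher, 3 were lower and 1 did not pass, median 1.10 (adjusted p = 0.022 with an estimated correlation), with the keratins KRT8 and KRT7 at 2.91 ± 0.095 and 2.53 ± 0.25. The list held 23 genes, and those not tested were hardly counted, such as GRHL2 with 8 and CLDN3 with 51 counts over all 12 libraries. For the common line effect the epithelial list did not pass (adjusted p = 0.056 with an estimated correlation). Of histone genes, 10 of 14 tested genes were higher, 0 were lower and 4 did not pass, median 0.63 (adjusted p = 0.034 with an estimated correlation), with H1-2 at 1.16 ± 0.078. Where no second count stands, the count adjusted over the list alone was equal.

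The remaining lists did not pass the list test under vehicle. Of secreted inflammatory factors, 13 of 21 tested genes were higher, 6 were lower and 2 did not pass, median 0.72, with adjusted p = 0.19 with an estimated correlation. IL1B stood at 4.85 ± 0.23 and IL1A at 4.03 ± 0.38, whereas the proteases MMP10 and MMP1 stood at -4.80 ± 0.1 and -3.35 ± 0.16. In the hypoxia and glycolysis list, 15 of 22 tested genes were higher, 4 were lower and 3 did not pass (16 and 4 adjusted over the list alone), median 0.50, with adjusted p = 0.18 with an estimated correlation, the angiogenic factor VEGFA at 2.37 ± 0.06 and CA12 at -2.47 ± 0.21. Of lysosome genes, 17 of 25 tested genes were higher, 2 were lower and 6 did not pass, median 0.33, with adjusted p = 0.37 with an estimated correlation and the protease CTSL at 1.11 ± 0.064. The DNA replication list leaned lower, as 2 of 37 tested genes were higher, 24 were lower and 11 did not pass (2 and 26 adjusted over the list alone), median -0.22, with adjusted p = 0.37 with an estimated correlation and CCNE2 at -0.83 ± 0.16. In the mitosis list, 1 of 31 tested genes were higher, 17 were lower and 13 did not pass, median -0.17, with adjusted p = 0.38 with an estimated correlation and the kinesin KIF11 at -0.84 ± 0.11. Of homologous recombination genes, 0 of 22 tested genes were higher, 10 were lower and 12 did not pass, median -0.23, with adjusted p = 0.61 with an estimated correlation and BRCA2 at -1.22 ± 0.24. Of basal-like tumour genes, 5 of 8 tested genes were higher, 2 were lower and 1 did not pass, median 1.67 and mean 0.31, with adjusted p = 0.19 with an estimated correlation and KRT15 at 2.34 ± 0.063. SCEL, named above among the genes lower in E5 cells, belongs to this list too. The list held 24 genes, and those not tested were hardly counted, such as KRT14 with 0 and KRT5 with 56 counts over all 12 libraries. Of ribosomal protein genes, 0 of 28 tested genes were higher, 17 were lower and 11 did not pass (0 and 19 adjusted over the list alone), median -0.20, with adjusted p = 0.64 with an estimated correlation. Where no second count stands, the count adjusted over the list alone was equal.

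Among genes tied to the drugs, the pumps ABCB1 and ABCC2 were higher in E5 vehicle cells at 1.98 ± 0.24 and 1.43 ± 0.11. TOP1 was lower at -0.53 ± 0.072, SLC29A1 at -0.84 ± 0.087, DPYD at -0.98 ± 0.073, TYMS at -0.29 ± 0.06, TOP2A at -0.46 ± 0.13 and MKI67 at -0.40 ± 0.085. Differences in MDM2 (0.06 ± 0.09, adjusted p = 0.62), GDF15 (0.06 ± 0.14, adjusted p = 0.77), TK1 (-0.06 ± 0.089, adjusted p = 0.61), CES2 (0.03 ± 0.092, adjusted p = 0.82) and ATP7B (0.11 ± 0.16, adjusted p = 0.61) did not pass. CDKN1A (0.24 ± 0.092, adjusted p = 0.041) passed with all libraries, but not without control vehicle replicate 1 (0.27) or 2 (0.17) or E5 vehicle replicate 1 (0.22), 2 (0.25) or 3 (0.25). The test called 6934 genes, 3457 higher and 3477 lower in E5 cells, with 1162 and 787 at least 2-fold.

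Under FOLFIRINOX, E5 cells again had more antigen presentation and NRF2 target transcripts than control cells. HLA-DRA stood at 1.27 ± 0.395 CPM in control and 98.6 ± 5.72 CPM in E5 libraries (6.17 ± 0.14, adjusted p = 3e-15). NQO1, a quinone reductase (ENSG00000181019.13, chromosome 16, 69706996 to 69726668), stood at 165 ± 8.01 and 979 ± 50.6 CPM, log2 2.56 ± 0.058, adjusted p = 2.4e-15. The aldehyde dehydrogenases parted, as ALDH1A1 (ENSG00000165092.13, chromosome 9, 72900671 to 73080442) was lower at -4.81 ± 0.11, adjusted p = 3.6e-15 and ALDH1A3 (ENSG00000184254.17, chromosome 15, 100877714 to 100916626) higher at 4.56 ± 0.076, adjusted p = 1.2e-16.

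Of the genes with the highest folds under drug, AQP4 had 0 counts in control libraries and was at least 96.9-fold higher in E5 cells. HLA-DPB1 was 95.9-fold (95% interval 32.5 to 468) higher. ARHGAP20 stood at 7.68 ± 0.17, GDA at 7.13 ± 0.13, NRXN3 at 6.77 ± 0.22, CD74 at 5.95 ± 0.13, SAMD9L at 5.68 ± 0.4, VCAM1 at 5.37 ± 0.32 and the nucleotide receptor P2RY6 at 5.36 ± 0.34. In the other direction, SCEL was 338-fold (95% interval 93.1 to 2790), PTPRC 267-fold (95% interval 73.4 to 2210) and SULT1B1 255-fold (95% interval 70.3 to 2120) lower in E5 cells. RAB34 stood at -7.04 ± 0.33, MMP10 at -5.19 ± 0.11, MMP1 at -4.86 ± 0.13, ZNF334 at -5.05 ± 0.35, the decoy receptor IL13RA2 at -4.80 ± 0.27 and the actin-capping protein CAPG at -4.71 ± 0.28.

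Of the antigen presentation list, 20 of 20 tested genes were higher, 0 were lower and 0 did not pass under FOLFIRINOX, median 1.27 (adjusted p = 0.0032 with an estimated correlation), with CIITA at 3.80 ± 0.2. Of NRF2 targets, 18 of 19 tested genes were higher, 0 were lower and 1 did not pass, median 1.22 (adjusted p = 0.0025 with an estimated correlation), with AKR1B10 at 3.85 ± 0.23 and PIR at 3.01 ± 0.077. Of interferon-stimulated genes, 25 of 31 tested genes were higher, 2 were lower and 4 did not pass, median 1.35, with adjusted p = 0.066 with an estimated correlation. OAS2 stood at 5.31 ± 0.22, RSAD2 was 31.3-fold (95% interval 10.4 to 154) higher, and BST2, with 0 counts in control libraries, was at least 4.06-fold higher. Secreted inflammatory factors leaned lower in E5 cells, as 7 of 21 tested genes were higher, 12 were lower and 2 did not pass, median -0.61, with adjusted p = 0.06 with an estimated correlation. The cytokine IL11 stood at -4.11 ± 0.15 and CXCL5 at -3.18 ± 0.2. Counts adjusted over the list alone were equal for these lists.

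Proliferation and stress lists also leaned lower in E5 cells under drug, without a passing list test. In the mitosis list, 0 of 31 tested genes were higher, 27 were lower and 4 did not pass, median -0.52, with adjusted p = 0.14 with an estimated correlation, HMMR at -1.21 ± 0.14 and the kinetochore protein NDC80 at -0.88 ± 0.095. Of p53 targets, 5 of 31 tested genes were higher, 15 were lower and 11 did not pass, median -0.25, with adjusted p = 0.32 with an estimated correlation, EDA2R at -1.82 ± 0.15 and GADD45A at -1.36 ± 0.071. Of ATF4 targets, 5 of 21 tested genes were higher, 11 were lower and 5 did not pass, median -0.30, with adjusted p = 0.63 with an estimated correlation and DDIT3 at -1.14 ± 0.089. Of BCL2 family genes, 5 of 19 tested genes were higher, 12 were lower and 2 did not pass, median -0.24, with adjusted p = 0.63 with an estimated correlation and the survival gene BCL2A1 at -1.83 ± 0.12. Of ribosome biogenesis genes, 1 of 26 tested genes were higher, 15 were lower and 10 did not pass, median -0.19, with adjusted p = 0.16 with an estimated correlation and NOLC1 at -0.62 ± 0.048. Of homologous recombination genes, 2 of 22 tested genes were higher, 10 were lower and 10 did not pass, median -0.22, with adjusted p = 0.74 with an estimated correlation and the helicase BLM at -0.49 ± 0.086. Several lists leaned higher. Of epithelial genes, 6 of 13 tested genes were higher, 3 were lower and 4 did not pass, median 0.76, with adjusted p = 0.17 with an estimated correlation and the cadherin CDH3 at 1.70 ± 0.084. In the hypoxia and glycolysis list, 13 of 22 tested genes were higher, 5 were lower and 4 did not pass, median 0.60, with adjusted p = 0.16 with an estimated correlation, VEGFA at 2.99 ± 0.061 and the glucose transporter SLC2A1 at 1.78 ± 0.082. In the stemness list, 8 of 14 tested genes were higher, 5 were lower and 1 did not pass (8 and 6 adjusted over the list alone), median 0.39, with adjusted p = 0.24 with an estimated correlation and the transcription factor SOX2 at 1.10 ± 0.078. Of basal-like tumour genes, 6 of 8 tested genes were higher, 2 were lower and 0 did not pass, median 1.5 and mean 0.12, with adjusted p = 0.16 with an estimated correlation. Of cholesterol synthesis genes, 10 of 22 tested genes were higher, 5 were lower and 7 did not pass (11 and 5 adjusted over the list alone), median 0.22, with adjusted p = 0.43 with an estimated correlation and STARD4 at 3.32 ± 0.15. Where no second count stands, the count adjusted over the list alone was equal.

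Among genes tied to the drugs, ABCG2 was higher in E5 cells under FOLFIRINOX at 3.07 ± 0.068, adjusted p = 2.1e-15. By counts ABCB1 stood at 1.24 ± 0.23 and ABCC2 at 0.43 ± 0.09, calls lost on the authors' FPKM (ABCB1 0.12 and 0.28, ABCC2 0.32 and 0.42). TOP1 was lower at -0.71 ± 0.072, TOP2A at -0.53 ± 0.13, MKI67 at -0.48 ± 0.085 and SLC29A1 at -0.36 ± 0.081. DPYD was higher by counts at 0.37 ± 0.074 and lower by the authors' FPKM (-0.25 and -0.26). MDM2 was higher at 0.51 ± 0.093, a call lost by FPKM (0.20). CDKN1A was lower at -0.29 ± 0.088, a call lost without control FOLFIRINOX replicate 2 (-0.18). TYMS stood at -0.14 ± 0.06, adjusted p = 0.049, a call that was lost on leaving out any single library except control vehicle replicate 3 or E5 FOLFIRINOX replicate 1 (-0.11 to -0.15). GDF15 (-0.06 ± 0.16, adjusted p = 0.77), TK1 (-0.08 ± 0.093, adjusted p = 0.51), CES2 (0.01 ± 0.093, adjusted p = 0.91) and ATP7B (-0.06 ± 0.16, adjusted p = 0.76) did not pass with all libraries, and TK1 passed with the GC correction (-0.16). Of the named genes past the test, TOP2A, CENPE, BRCA2 and ALDH3A1 had libraries that overlapped between the groups. The test called 8488 genes, 4170 higher and 4318 lower, with 1235 and 1096 at least 2-fold. On log2(FPKM + 1) the all-gene median lay at -0.12, and 2465 genes were higher and 4495 lower.

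Whether E5 and control cells answered FOLFIRINOX differently was tested as the difference of their log2 responses. As lists, histone genes, secreted inflammatory factors and interferon-stimulated genes responded more negatively in E5 than in control cells. Median line effects, E5 against control, under vehicle and under FOLFIRINOX were 0.63 and 0.16 for histone genes. For secreted inflammatory factors these medians were 0.72 and -0.61, and for interferon-stimulated genes 2.45 and 1.35. CXCL8, a neutrophil chemokine (ENSG00000169429.11, chromosome 4, 73740541 to 73743716), went from 8.85 ± 1.42 to 73.1 ± 3.54 CPM in control cells and from 14.1 ± 1.15 to 20.9 ± 0.98 CPM in E5 cells, a difference of -2.53 ± 0.14, adjusted p = 7.4e-09. PADI2 went from 466 ± 13.8 to 20.2 ± 2.42 CPM in control cells and from 237 ± 7.75 to 61.1 ± 3.62 CPM in E5 cells (2.59 ± 0.11, adjusted p = 1.6e-10).

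Of secreted inflammatory factors, 1 of 21 tested genes responded more positively, 17 more negatively and 3 did not pass (1 and 18 adjusted over the list alone) in E5 cells, with a median difference of -1.02 (adjusted p = 0.0094 with an estimated correlation), IL11 at -2.25 ± 0.34 and CXCL1 at -2.16 ± 0.23. Of interferon-stimulated genes, 0 of 31 tested genes responded more positively, 19 more negatively and 12 did not pass, median -1.01 (adjusted p = 0.015 with an estimated correlation), with the chemokine CCL5 at -3.11 ± 0.3 and MX1 at -2.19 ± 0.2. The latter count was equal when adjusted over the list alone. Of histone genes, 0 of 14 tested genes responded more positively, 8 more negatively and 6 did not pass (0 and 10 adjusted over the list alone), median -0.48 (adjusted p = 0.023 with an estimated correlation), with H2BC4 at -1.35 ± 0.18 and H2AC11 at -1.07 ± 0.14.

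Other lists held genes called by the difference test without a passing list test. Of all tested genes, 25.7% were called, and some of these lists lay not far above that share. In the antigen presentation list, 1 of 20 tested genes responded more positively, 11 more negatively and 8 did not pass (equal counts adjusted over the list alone), median -0.59, with adjusted p = 0.058 with an estimated correlation. HLA-B stood at -1.93 ± 0.11 and HLA-F at -1.92 ± 0.25. Of NRF2 targets, 11 of 19 tested genes responded more positively, 1 more negatively and 7 did not pass (12 and 2 adjusted over the list alone), median 0.38, with adjusted p = 0.079 with an estimated correlation, PIR at 2.24 ± 0.099 and NQO1 at 0.88 ± 0.078. Of ATF4 targets, 3 of 21 tested genes responded more positively, 11 more negatively and 7 did not pass (4 and 11 adjusted over the list alone), median -0.52, with adjusted p = 0.18 with an estimated correlation, ATF3 at -1.86 ± 0.12 and DDIT3 at -1.49 ± 0.13. Of ribosomal protein genes, 26 of 28 tested genes responded more positively, 0 more negatively and 2 did not pass (27 and 0 adjusted over the list alone), median 0.37, with adjusted p = 0.24 with an estimated correlation and RPL10 at 0.66 ± 0.094. Of p53 targets, 2 of 31 tested genes responded more positively, 10 more negatively and 19 did not pass (3 and 12 adjusted over the list alone), median -0.21, with adjusted p = 0.083 with an estimated correlation, GADD45A at -1.77 ± 0.11 and the kinase PLK2 at -1.29 ± 0.079. In the mitosis list, 0 of 31 tested genes responded more positively, 11 more negatively and 20 did not pass (0 and 13 adjusted over the list alone), median -0.21, with adjusted p = 0.19 with an estimated correlation and CDC25C at -1.02 ± 0.11. Of lysosome genes, 1 of 25 tested genes responded more positively, 8 more negatively and 16 did not pass (1 and 12 adjusted over the list alone), median -0.22, with adjusted p = 0.27 with an estimated correlation and NEU1 at -1.27 ± 0.12. Of chaperones, 1 of 18 tested genes responded more positively, 6 more negatively and 11 did not pass (2 and 6 adjusted over the list alone), median -0.14, with adjusted p = 0.083 with an estimated correlation and HERPUD1 at -1.0 ± 0.096. In the stemness list, 5 of 14 tested genes responded more positively, 4 more negatively and 5 did not pass (7 and 4 adjusted over the list alone), median 0.31 but mean -0.04, with adjusted p = 0.24 with an estimated correlation and SOX2 at 1.93 ± 0.11. Of BCL2 family genes, 2 of 19 tested genes responded more positively, 5 more negatively and 12 did not pass (3 and 6 adjusted over the list alone), median -0.23, with adjusted p = 0.42 with an estimated correlation. Of MAPK and AP-1 output genes, 2 of 21 tested genes responded more positively, 5 more negatively and 14 did not pass (2 and 6 adjusted over the list alone), median -0.18, with adjusted p = 0.5 with an estimated correlation and DUSP5 at -1.52 ± 0.13.

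Among genes of at least 5 CPM in any library, the largest positive differences belonged to PRKG1 (3.30 ± 0.39), the adhesion molecule CNTN1 (3.15 ± 0.37), the complement proteases C1S (2.90 ± 0.18) and C1R (2.42 ± 0.42) and SNED1 (2.88 ± 0.23). FSTL5 (2.5 ± 0.24), the calcium channel subunit CACNG4 (2.5 ± 0.26) and the granule protein SCG2 (2.27 ± 0.091) followed. P2RY6 (2.32 ± 0.6, adjusted p = 0.0081) passed with all reads but not after thinning to the depth of the shallowest library (2.14) or on the authors' FPKM (0.11 and 0.71). The largest negative differences included the lipase LIPG (-3.82 ± 0.42), the protease CTSS (-3.16 ± 0.28), CCL5, DACT1 (-3.04 ± 0.28) and the chemokine receptor CXCR4 (-3.03 ± 0.44, but -0.57 without a call on log2(FPKM + 1)). IFI44L (-4.75 ± 1, adjusted p = 0.0029) lost its call without control FOLFIRINOX replicate 3 (-3.78), and IFITM1 (-3.02 ± 0.87, adjusted p = 0.016) lost it without control FOLFIRINOX replicate 2 (-2.30), after thinning (-2.38) and on log2(FPKM + 0.1) (-2.55). The transcription factor MSC (fitted -4.55) and NRXN3 (fitted -4.31) had 0 counts and LAMA4 (fitted -3.35) 1 count in control vehicle libraries, so their fitted differences depend on the prior count. MSC turned to 0.58 on log2(FPKM + 1), 0.11 on rlog values and 0.04 with a prior count of 10, NRXN3 to 0.21 on log2(FPKM + 1) and 0.05 on rlog values, and LAMA4 to 0.04 on rlog values. MSC also lost its call without control FOLFIRINOX replicate 2 (-4.11) or control vehicle replicate 2 (-4.5), after thinning (-3.67) and on log2(FPKM + 0.1) (-0.67), NRXN3 without control FOLFIRINOX replicate 3 (-3.46) or control vehicle replicate 2 (-4.26), after thinning (-3.91) and on log2(FPKM + 0.1) (-0.05), and LAMA4 without control FOLFIRINOX replicate 3 (-2.35) or control vehicle replicate 3 (-2.84) and on FPKM (-1.12 and -0.16).

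Among genes tied to the drugs, the response of DPYD was more positive in E5 cells (1.35 ± 0.1, adjusted p = 1.9e-07), and that of CDKN1A more negative (-0.54 ± 0.13, adjusted p = 0.0055). ABCC2 (-1.0 ± 0.14, adjusted p = 7.9e-05, but -0.18 and -0.37 without a call by FPKM) and ABCG2 (-0.36 ± 0.092, adjusted p = 0.0085, but -0.16 without a call on rlog values) were more negative. SLC29A1 (0.48 ± 0.12, adjusted p = 0.0073) and MDM2 (0.45 ± 0.13, adjusted p = 0.017) were more positive by counts, with their calls lost by FPKM (0.27 and 0.29 for SLC29A1, 0.13 for MDM2). GDF15 (-0.12 ± 0.21, adjusted p = 0.72), MKI67 (-0.08 ± 0.12, adjusted p = 0.68), TOP2A (-0.07 ± 0.18, adjusted p = 0.83), TK1 (-0.01 ± 0.13, adjusted p = 0.95), CES2 (-0.01 ± 0.13, adjusted p = 0.95), ATP7B (-0.18 ± 0.23, adjusted p = 0.61) and ABCB1 (-0.75 ± 0.35, adjusted p = 0.16) did not pass. TYMS (0.14 ± 0.084, adjusted p = 0.23) and TOP1 (-0.17 ± 0.1, adjusted p = 0.23) passed with the GC correction alone (0.20 and -0.22). The test called 4013 genes, 2080 more positive and 1933 more negative in E5 cells, with 354 and 509 at least 2-fold. On log2(FPKM + 1) the all-gene median lay at -0.11, and 705 genes were more positive and 1999 more negative.

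**Figure D3:**
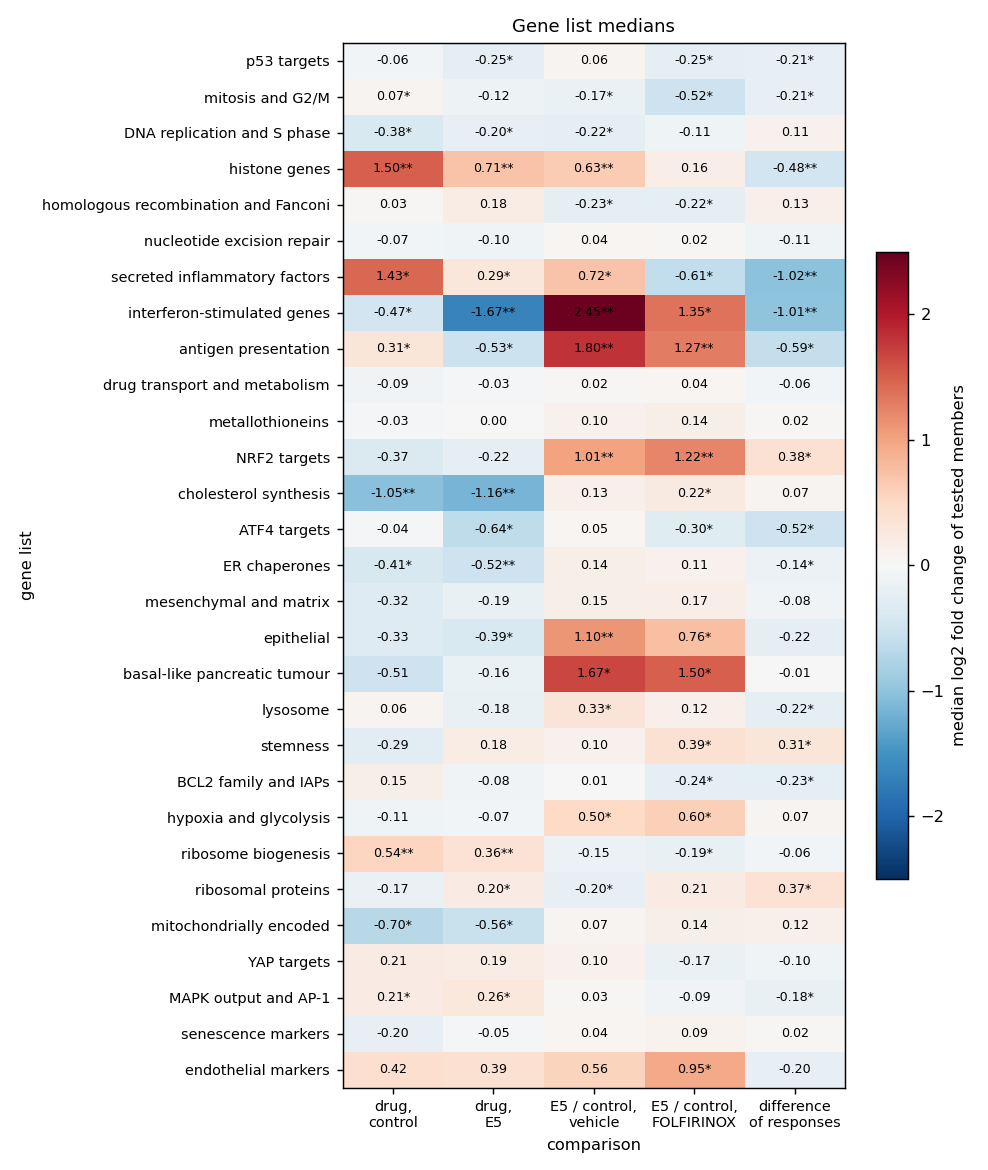
Heatmap of the median log2 fold change of gene lists (y axis) in each comparison (x axis), with the colour scale in log2 units. A single star marks a median outside the central 95% of random lists matched on expression and a double star a list test that also passed with an estimated correlation, such as cholesterol synthesis at -1.05 in control cells and interferon-stimulated genes at 2.45 between the lines under vehicle.

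The drug responses of the lines were compared across genes. Of the genes called higher with drug, 2990 were shared by both lines, against 1274 for independent lists, and of those called lower 3253, against 1394. Across 15119 genes of at least 1 CPM the responses had Pearson r = 0.74 and Spearman rho = 0.73, where genes are not independent replicates, and 20 simulations without a drug effect gave r of -0.034 to 0.034. The slope of E5 on control responses was 0.67 by total least squares. Of the 4013 genes called by the difference test, the response was smaller in size in E5 cells for 3115 and larger for 898. Interferon-stimulated genes had a larger median change in E5 cells (-1.67) than in control cells (-0.47, or -0.31 with BST2 at its floor bound). They started from unlike levels, with a median line effect of 2.45 under vehicle, higher in E5 cells. Line effects under vehicle and under FOLFIRINOX had r = 0.79, rho = 0.59 and a slope of 0.93. They shared 2337 genes called higher in E5 cells, against 922 for independent lists, and 2078 called lower, against 960.

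**Figure D4:**
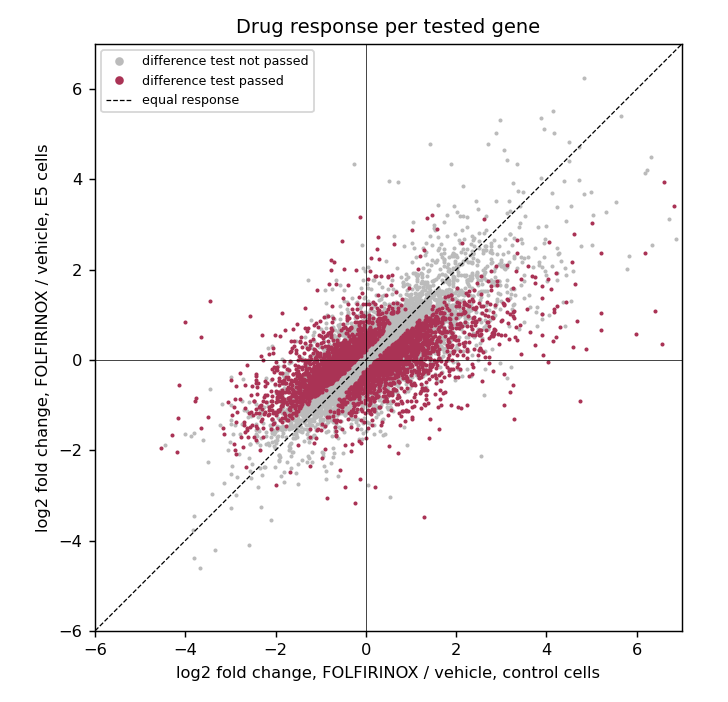
Log2 fold change with FOLFIRINOX in control cells (x axis) against that in E5 cells (y axis), where each point is a gene, red points passed the test of the difference and the dashed line marks equal responses. The points follow a slope of 0.67, below the dashed line's, with r = 0.74.

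Effects common to both lines were tested as the mean of the drug effects in control and E5 cells. A gene that changed in a single line could therefore pass. With FOLFIRINOX, TXNIP (3.70 ± 0.053, adjusted p = 9e-18), HDAC9 (2.87 ± 0.062), PLK2 (1.63 ± 0.04), the stress gene GADD45A (2.16 ± 0.054), APOE (2.99 ± 0.078), the GTPase GEM (1.65 ± 0.045) and H2AC6 (1.67 ± 0.049) rose. So did the noncoding RNAs SNHG1 (1.5 ± 0.037), LUCAT1 (2.33 ± 0.064) and LINC00973 (2.35 ± 0.066). PADI2 (-3.25 ± 0.055, adjusted p = 8.6e-17), the desaturase SCD (-2.52 ± 0.044), PIR (-2.38 ± 0.05), the dehydrogenase IDH1 (-2.03 ± 0.046) and INSIG1 (-2.17 ± 0.05) fell, as did PSAT1 (-1.69 ± 0.04), SLC2A12 (-1.87 ± 0.046), the hedgehog receptor PTCH1 (-2.32 ± 0.06) and MAGED1 (-1.87 ± 0.049). List tests passed with an estimated correlation for cholesterol synthesis (median -1.07, 0 of 22 tested genes rose, 22 fell and 0 did not pass, adjusted p = 0.0031 with an estimated correlation), ribosome biogenesis (median 0.45, 20 of 26 tested genes rose, 0 fell and 6 did not pass, adjusted p = 0.008 with an estimated correlation), histone genes (median 1.09, 13 of 14 tested genes rose, 0 fell and 1 did not pass, adjusted p = 0.0088 with an estimated correlation) and chaperones (median -0.55, 1 of 18 tested genes rose, 16 fell and 1 did not pass, adjusted p = 0.011 with an estimated correlation). These counts were equal when adjusted over the list alone. The test called 10713 genes, 5331 higher and 5382 lower, with 1333 and 835 at least 2-fold. On log2(FPKM + 1) 5900 were higher and 3398 lower.

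Averaged over both treatments, ALDH1A3 (4.30 ± 0.052, adjusted p = 3.6e-19), GDA (7.72 ± 0.094), CD74 (6.01 ± 0.088), ABCG2 (3.25 ± 0.049), ARHGAP20 (8.71 ± 0.14), HLA-DRA (6.44 ± 0.1) and VEGFA (2.68 ± 0.043) were higher in E5 cells. GRIP1 (5.33 ± 0.087), LRATD2 (5.11 ± 0.086) and the interferon-inducible GTPase GBP4 (5.15 ± 0.088) completed the genes of smallest p. MMP10 (-4.99 ± 0.075, adjusted p = 4.2e-18), ALDH1A1 (-4.45 ± 0.076), MMP1 (-4.11 ± 0.1), the protease inhibitor TIMP2 (-2.28 ± 0.049), MME (-5.15 ± 0.12) and TRHDE (-5.18 ± 0.13) were lower, as were CPED1 (-5.14 ± 0.094), MARCHF4 (-3.92 ± 0.085), LINC02154 (-6.67 ± 0.16) and DOCK4 (-2.10 ± 0.052). List tests passed for antigen presentation (median 1.51, 20 of 20 tested genes were higher, 0 were lower and 0 did not pass, adjusted p = 0.0011 with an estimated correlation), NRF2 targets (median 1.08, 18 of 19 tested genes were higher, 0 were lower and 1 did not pass, adjusted p = 0.0011 with an estimated correlation) and interferon-stimulated genes (median 1.85, 27 of 31 tested genes were higher, 0 were lower and 4 did not pass, adjusted p = 0.014 with an estimated correlation), with equal counts adjusted over the list alone. The test called 9059 genes, 4481 higher and 4578 lower, with 1117 and 860 at least 2-fold. On log2(FPKM + 1) 3051 were higher and 4528 lower, and with total counts only 3937 and 5217. Across genes the common drug and line effects had r = -0.11 (-0.21 on log2(FPKM + 1)), rho = -0.23 and a covariance of -0.0764. Simulations without any effect gave r of -0.119 to -0.074, rho of -0.075 to -0.049 and a covariance of -0.00209 to -0.0013. They held noise alone, so they show what noise gives and not how unrelated real effects would correlate.

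The drug response was also set against gene length. In control cells the shortest of 10 bins of genes (median 1.38 kb) had a median log2 fold change of 0.13 and the longest (257 kb) of -0.16, with rho = -0.11 across 15636 genes. In E5 cells the same bins stood at 0.15 and 0.05 (rho = -0.02), and the difference rose with length (rho = 0.15). Over 9995 protein-coding genes of at least 10 CPM, rho for the difference was 0.23. For those genes the shortest and longest bins stood at 0.06 and -0.31 in control cells and at 0.04 and -0.05 in E5 cells. The control rho was -0.06 without control FOLFIRINOX replicate 2. The E5 rho was -0.05 without E5 vehicle replicate 1, -0.01 without E5 vehicle replicate 2 or 3 and -0.10 after GC correction.

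Line effects were shifted together over stretches of chromosomes. On chromosome 10, 135 tested genes between 43.6 and 73.4 Mb had a median common line effect of -0.43 and 273 genes between 87.8 and 133 Mb one of -0.42. On chromosome 16, 132 genes between 31.9 and 68.2 Mb stood at -0.42 and 98 genes between 70 and 87.3 Mb at -0.41. Genes at 0.109 to 14.1 Mb of chromosome 18 (65 genes) stood at -0.46, 76 genes of chromosome 4 that end at 155 Mb at -0.28, and those at 25.1 to 44 Mb of chromosome 7 (93 genes) at 0.40. Of 14453 windows of 51 neighbouring tested genes, 365 lay beyond the largest of 1000 shuffles of gene order for the line effect and 24 for the drug effect.

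**Figure D5:**
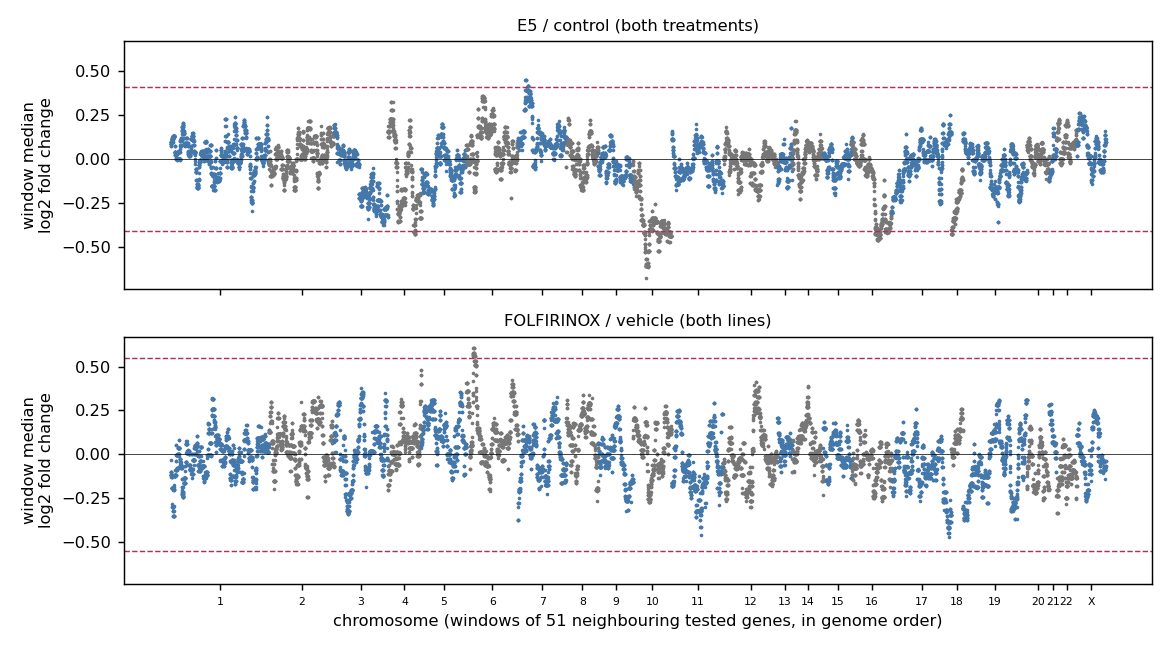
Median log2 effect in windows of 51 neighbouring tested genes along the chromosomes (x axis, genome position), with E5 against control over both treatments at the top and FOLFIRINOX against vehicle over both lines at the bottom. Dashed lines mark the largest of 1000 shuffles of gene order (0.41 at the top, 0.55 at the bottom), and the line effect had 365 windows beyond them.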

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

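The tests of leukocyte markers and of other splits of the libraries were chosen only after the results were seen.

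The drug response differed between E5 and control cells in 4013 genes, listed here since the lines differed beyond the test's threshold. Of 100 drawn splits, the real one included, 5 gave as many genes, with 6062 as the highest other, and this count did not exclude chance. The splits have a structure: 17 of them keep or mirror the real labels within a line or treatment and so carry the drug or line effect itself. All 5 large ones are among these, and the others gave at most 0 genes, so the count of 5 is no test of chance alone.

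List medians were included because the difference between the lines passed camera: -0.48 for histone genes, -1.02 for secreted inflammatory factors and -1.01 for interferon-stimulated genes. Among genes that passed the test and reached 5 CPM in any library, those with the largest fitted differences between the lines were listed too. Responses were more positive in E5 cells for PRKG1 (3.30), CNTN1 (3.15), C1S (2.90), SNED1 (2.88), PADI2 (2.59), FSTL5 (2.5), CACNG4 (2.5), C1R (2.42), P2RY6 (2.32) and SCG2 (2.27). They were more negative for IFI44L (-4.75), MSC (-4.55), NRXN3 (-4.31), LIPG (-3.82), LAMA4 (-3.35), CTSS (-3.16), CCL5 (-3.11), DACT1 (-3.04), CXCR4 (-3.03) and IFITM1 (-3.02). As stated above, the values of MSC, NRXN3 and LAMA4 depended on the prior count and changed sign under some settings. P2RY6, IFI44L, CXCR4 and IFITM1 lost their calls under some settings.

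Reads ambiguous between genes entered no comparison, and their share had a higher mean with drug in both lines. Their mean share was 3.15% in control FOLFIRINOX libraries (3.13 to 3.18) against 2.95% with vehicle (2.86 to 3.04), and 3.11% in E5 FOLFIRINOX libraries (3.04 to 3.20) against 2.97% (2.90 to 3.03).

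Immune genes differed between the lines, with antigen presentation at a median of 1.80 and interferon-stimulated genes at 2.45 under vehicle. Leukocytes in the E5 cultures were argued against by PTPRC, whose fitted log2 line effect was -9.63, with the higher level in control cells. Leukocytes in the control cultures were argued against too, as 0 of the 11 other leukocyte markers reached 1 CPM there, while PTPRC stood at 51.9 CPM. Interferon gene transcripts numbered 2 counts over the E5 vehicle libraries and 0 over the control ones, too few to tell whether E5 cells make interferon. A difference within the tumour cells may remain as a hypothesis, and its cause was not tested.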

How the results depend on the processing

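The GC correction, the limma and DESeq2 settings of the correlations and the list tests by camera were chosen only after the results were seen.

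Requiring a fold of at least 2 as well left 3113 genes for the drug in control cells, 1595 in E5 cells, 1949 between the lines under vehicle, 2331 under FOLFIRINOX, 863 for the difference, 2168 for the common drug effect and 1977 for the common line effect. For the difference, log2(FPKM + 0.1) gave 2468 genes, thinning 2991, DESeq2 3605, no filter 3723 and the GC correction 5428. Scaling by total counts moved the all-gene median by 0.14 for the drug in control cells and by 0.11 for the common drug effect. It gave 6206 genes higher and 3991 lower in control cells, and 1596 and 2448 for the difference. Leaving out single libraries gave 9336 to 10288 genes for the drug in control cells, 7263 to 8663 in E5 cells, 5912 to 7424 between the lines under vehicle, 7629 to 8517 under FOLFIRINOX, 3247 to 4057 for the difference, 10325 to 10795 for the common drug effect and 8530 to 9268 for the common line effect.

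The correlation of drug responses between lines was 0.79 for genes of at least 10 CPM, 0.75 with a prior count of 10 and 0.71 to 0.74 without single libraries. That of drug and line effects was -0.14 for genes of at least 10 CPM, -0.21 on log2(FPKM + 1), -0.15 with a prior count of 10 and -0.14 to -0.08 without single libraries. For gene length, rho in control cells was -0.15 with the GC correction, -0.16 for protein-coding genes of at least 10 CPM and -0.14 to -0.06 without single libraries. In E5 cells it was -0.10 with the GC correction and -0.05 to -0.01 without single libraries.

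Directions turned for some genes of low count and between counts and FPKM, and the cause was not tested. DPYD between the lines under FOLFIRINOX was -0.26 on log2(FPKM + 0.1) and -0.25 on log2(FPKM + 1), and PSMB10 with drug in control cells 0.12 and 0.11. The epithelial list's common drug effect was 0.23 on log2(FPKM + 1). For the difference, LAMA4 was 0.04 on rlog values. MSC was 0.58 on log2(FPKM + 1), 0.11 on rlog values and 0.04 with a prior count of 10, and NRXN3 0.21 on log2(FPKM + 1) and 0.05 on rlog values.

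Of the 95 pairs of list and comparison outside the range of random lists, log2(FPKM + 1) lost 20 and gained 7, the GC correction lost 8 and gained 8, and a prior count of 10 lost 7 and gained 2. Leaving out single libraries lost 2 to 11 of them, the most without control FOLFIRINOX replicate 2, and no setting moved a pair to the opposite side.

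The library number as a replicate block gave 9988, 7905, 6635 and 8145 genes for the drug in control and E5 cells and the lines under vehicle and FOLFIRINOX. The block gave 3538 for the difference, 10524 and 8775 for the common drug and line effects, and 97 of 203 pairs of list and comparison outside the range of random lists. With the block, 4 named calls were lost, those of TOP2A (0.31) and SLC29A1 (0.20) with drug in control cells, CDKN1A (0.24) between the lines under vehicle and TYMS (-0.14) between the lines under FOLFIRINOX. Of 563 values of named genes, the other 559 kept their call and direction. Libraries of the same number did not deviate together: their 18 correlations ran from -0.62 to 0.52. These deviations were not corrected for GC, and 56.3% of their variance lay on the GC-linked axis described below. A weaker pairing beneath that axis was not tested.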

Other observations

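The tests of replicate number, of small nucleolar RNA host genes and of other splits were chosen only after the results were seen.

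More long noncoding RNAs rose than fell with FOLFIRINOX. In control cells 961 of 2083 rose and 220 fell (46.1% and 10.6%), and in E5 cells 643 rose and 177 fell, with medians of 0.54 and 0.32, while protein-coding genes had a median of -0.05 in control cells. Small nucleolar RNAs are spliced from introns of host genes. Of 24 such host genes, 15 rose and 3 fell in control cells (median 0.70), and 17 rose and 1 fell in E5 cells (median 0.66). Their common drug effect lay at percentile 100 of random lists. The class was chosen from the same data and camera was not run on it, so a rise as a class stays a hypothesis.

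Several lists showed no passing list test in either line's drug response. With drug in control cells, medians were -0.07 for nucleotide excision repair (5 of 19 tested genes rose, 4 fell and 10 did not pass (4 and 4 adjusted over the list alone)), -0.09 for drug transport and metabolism (7 of 24 tested genes rose, 9 fell and 8 did not pass) and -0.03 for metallothioneins (0 of 5 tested genes rose, 1 fell and 4 did not pass). YAP targets stood at 0.21 (10 of 20 tested genes rose, 6 fell and 4 did not pass), senescence markers at -0.20 (3 of 12 tested genes rose, 6 fell and 3 did not pass) and endothelial markers at 0.42 (1 of 5 tested genes rose, 0 fell and 4 did not pass). Mesenchymal and matrix genes had a median of -0.32 but a mean of 0.01 in control cells, stemness genes -0.29 and 0.08, and basal-like tumour genes -0.51 and 0.17. The classical tumour list had 3 tested genes, the leukocyte list 2 and the fibroblast list 4, too few for a median. Of 12 fibroblast markers, COL1A1 and COL3A1 reached 1 CPM in control vehicle, COL1A1 and MFAP5 in control FOLFIRINOX and COL1A1 in both E5 groups. Of 10 endothelial markers, 1 reached 1 CPM in control vehicle and 3 in E5 vehicle libraries. The endothelial cadherin CDH5 stood at 5.55 CPM in E5 vehicle and 0.153 CPM in control vehicle libraries, while ROBO4 went the other way (0.561 and 1.16 CPM). Of acinar, islet and hepatocyte markers, 0 of 12 reached 1 CPM in any group.

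The line effect was shifted over chromosome regions, with 365 windows beyond the shuffles for the line and 24 for the drug, an excess that a copy number difference between the lines predicted. GC content was argued against, as 202 windows stayed beyond the shuffles after correction. An effect of a single treatment was argued against by the size of the shift, which under FOLFIRINOX was 0.88 of that under vehicle over 249 windows. By number, 46 windows lay beyond the shuffles under FOLFIRINOX and 249 under vehicle, with limits of 0.55 and 0.44. Copy number may explain the regions as a hypothesis, and no DNA was analysed here.

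Libraries of different groups shared an axis with 56.3% of the variance within groups, whose loading followed transcript GC with rho = 0.87 over 9386 genes, as GC-dependent library preparation predicted. The tested effects followed GC too, with rho = -0.12 for the drug in control cells, -0.26 in E5 cells, 0.16 and 0.04 for the lines under vehicle and FOLFIRINOX, -0.11 for the difference, -0.19 for the common drug effect and 0.11 for the common line effect, and the GC correction, which is built to remove such trends, left -0.02 to 0.00. Transcript length (rho = -0.28) could not be told apart as a further source. Replicate number was argued against, with a median correlation of -0.19 over 18 same-number pairs and a lowest of -0.62. What made libraries differ in GC stays open, the axis may be technical, and part of the tested effects may share its source.

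Over all tested genes, the median response of the longest of 10 bins minus that of the shortest was -0.29 in control cells and -0.10 in E5 cells. This did not reach the size set for a topoisomerase I block. Among protein-coding genes of at least 10 CPM, the gap passed that size in control cells (0.06 to -0.31) but not in E5 cells (0.04 to -0.05). The question stays open.

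For the 4 comparisons of 2 groups, 10 splits are too few for a share under 0.05; in each, 1 split, the real one, reached the count. The real values and the highest others were 10203 and 0 for the drug in control cells, 8174 and 0 in E5 cells, 6934 and 1 between the lines under vehicle, and 8488 and 0 under FOLFIRINOX. Of 100 drawn splits, 1 reached the common drug effect (10713, highest other 6261) and 1 the common line effect (9059, highest other 3463). In each case this was the real split, which does not decide on chance for the reason given below. For each effect, 17 splits keep or mirror the real labels in part of the design, and the others gave at most 0 genes. Splits that mix the real groups hold the effects as spread between libraries, so their counts do not measure what chance alone gives. If the columns of a GEO sample repeat a single culture, these splits do not address chance between cultures.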
